A study of Mus musculus with 9 samples.

How the data were processed

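RNA was measured in 9 libraries of C2C12 cells after 96 h of differentiation, 3 with the control siRNA and 3 with each of the 2 siRNAs against Eya3, as the labels group them. The labels give myotubes as the cell type of all 9, while their source field says myoblasts for 8 and myotubes for 1. The siRNA sequences and the strandedness of the libraries are not given in the sources used here.

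The deposited tables hold 1 line per transcript, with length, effective length, length-scaled abundance (TPM) and estimated read counts. Per the file headers, the counts are expected counts, estimated reads that are not whole numbers and are not normalised, and the TPM values sum to the same total in every library. The deposited effective length, another unit, is in bases. The layout is that of the Salmon program, but the tool, its settings and its transcript annotation are not stated. The submitters' processing notes name mm10 and DESeq2, without versions. The tests had been planned for whole-number read counts before the data were examined.

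Transcripts were assigned to genes with GENCODE M21 (GRCm38, the same assembly as mm10), by identifier. Of 115088 transcripts, 114200 (99.23%) matched and 888 did not, which held 0.15% to 0.16% of the reads of each library. Expected counts were summed per gene over 47311 genes and rounded to whole numbers. The tables used here hold no transcripts of the mitochondrial chromosome. Reads on 5 nuclear pseudogenes of mitochondrial origin (Gm28661, Gm10925, Gm28437, Gm29216 and Gm28439), noticed in the data, were given as a share. Reads of close paralogues, such as the myosin heavy chains and actins, and of overlapping antisense genes can be assigned to the wrong member, and this could not be checked from the tables.

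Genes were kept with filterByExpr, which left 14405. Counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) on all 9 libraries with 1 mean per group. The contrasts were each siRNA against si-Ctrl, the mean of both against si-Ctrl, and si-Eya3#2 against si-Eya3#1. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 3.31% with 6 residual degrees of freedom. Standard errors are the absolute log2 fold change divided by the square root of F and are approximate. CPM values use the TMM-scaled library sizes. Depth was 21188250 to 30602826 estimated reads per library. Between replicates of a group, the chi-square per degree of freedom of the counts ran from 3.78 to 19.8, so no pair was a copy of another.

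Before the data were examined, 39 gene lists of 713 genes were fixed, and 37 with at least 3 measured genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation was run beside it, and its calls numbered 3, 0 and 2 for si-Eya3#1, si-Eya3#2 and their mean. The fry test was also run, and its results are not given here. Counts adjusted over the list alone are printed where they differ from those adjusted over all genes, and were otherwise equal. The named genes were the measured SIX-EYA-DACH genes, then the 10 that rose and the 10 that fell most with both siRNAs by the smaller of their log2 fold changes. The latter needed a mean of at least 5 CPM and all 6 knockdown libraries on the same side of the controls. For each siRNA, the 5 that rose and 5 that fell most were added among genes not called in the same direction with the other siRNA. These also had to differ between the siRNAs. Up to 4 members of each list were taken by the smallest p for the mean of both. Results of some genes that met these rules are not reported here. Gene models without an official symbol were skipped among the common and siRNA-specific genes. Further list members given as examples were chosen after their values were seen.

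The test was tested on simulated data drawn from the control means with 200 changed genes. For si-Eya3#1 it recovered 66% of changes of 1.25-fold, 72% of 1.5-fold, 90% of 2-fold and 94% of 3-fold among 14405 genes, and 8% of its calls were unchanged genes. For si-Eya3#2 these shares were 64%, 74%, 88% and 94%, with 6.43% unchanged, and for the mean of both 68%, 82%, 92% and 96%, with 6.11% unchanged. A simulated list moved by 1.25-fold was called, and 0 of 30 unmoved lists were. The genes were drawn independently, so this does not test false calls of lists whose genes move together.

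Alternatives fixed before the data were examined were median-of-ratios scaling, library totals, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, an estimated correlation, and each library left out in turn. Those chosen after seeing the data were a per-gene transcript length offset, a correction for length and GC content, 2 exclusions of ribosomal RNA-like genes, leaving Eya3 out of the SIX-EYA-DACH list, and leaving out si-Ctrl replicate 3 and si-Eya3#1 replicate 3 together. Figures were drawn with matplotlib 3.10.9.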

Results

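Polyadenylated RNA was sequenced from C2C12 cells, a mouse myoblast line whose cells leave the cell cycle and fuse into multinucleated myotubes when growth factors are withdrawn. RNA was taken after 96 h of differentiation. The cells had received a control siRNA (si-Ctrl) or 1 of 2 siRNAs against Eya3 (si-Eya3#1 and si-Eya3#2), and each of the 3 groups held 3 libraries that the labels call biological replicates. Eya3 encodes a protein tyrosine phosphatase that is also a transcriptional co-activator. The 9 libraries held between 21188250 (si-Ctrl replicate 3) and 30602826 (si-Ctrl replicate 2) estimated reads. A count of 0 in a library allowed a level of up to 0.0982 to 0.142 CPM (counts scaled to library size), which covers counting error only. Reads on ribosomal RNA-like genes made up 1.06% (si-Eya3#1 replicate 3) to 4.13% (si-Ctrl replicate 2) of the gene totals. The first and second principal components of log2 CPM held 29.2% and 17.6% of the variance. On the next component si-Ctrl replicate 3, the shallowest library, had a score of 23.51.

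The first question was how far each siRNA lowered Eya3 and whether its network partners moved. Eya3 (ENSMUSG00000028886.15, chromosome 4, 132638987 to 132724765, plus strand, mm10) stood at 64.2 ± 0.888 CPM in si-Ctrl, 24.6 ± 0.449 with si-Eya3#1 and 32.9 ± 1.27 with si-Eya3#2 (mean ± SD, n = 3 each). The log2 fold changes were -1.38 (standard error 0.0389, edgeR adjusted p = 2.32e-12) and -0.96 (0.0375, adjusted p = 4.12e-10). Eya3 remained higher with si-Eya3#2 than with si-Eya3#1 by 0.42 on the log2 scale (adjusted p = 4.19e-06). The homeodomain factor gene Six4 (chromosome 12, 73099609 to 73113456, minus strand) fell by 0.31 and 0.37 (adjusted p = 2.77e-05 and 1.1e-05). Eya4, a paralogue of Eya3, fell by 0.13 with si-Eya3#1 (adjusted p = 0.00712) and rose by 0.16 with si-Eya3#2 (adjusted p = 0.00233). Eya1 was at -0.05 with si-Eya3#1 (adjusted p = 0.542) and rose by 0.19 with si-Eya3#2 (adjusted p = 0.0275). Six5, at 3.24 CPM, was at -0.13 and 0.16 (adjusted p = 0.615 and 0.564). Eya2 had 0 counts in all 9 libraries, and Six2, Dach1 and Dach2 had at most 2 counts in any library. The SIX-EYA-DACH list was lower by camera with both (adjusted p = 3.64e-09 and 4.99e-05). With an estimated correlation the call held for si-Eya3#1 (adjusted p = 0.0494) and not for si-Eya3#2 (adjusted p = 0.113), and Eya3 itself is a member. Without Eya3, a choice made after seeing the data, the list was called lower with si-Eya3#1 (adjusted p = 0.0144, and adjusted p = 0.234 with an estimated correlation) and not called with si-Eya3#2 (adjusted p = 0.403).

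**Figure D1:**
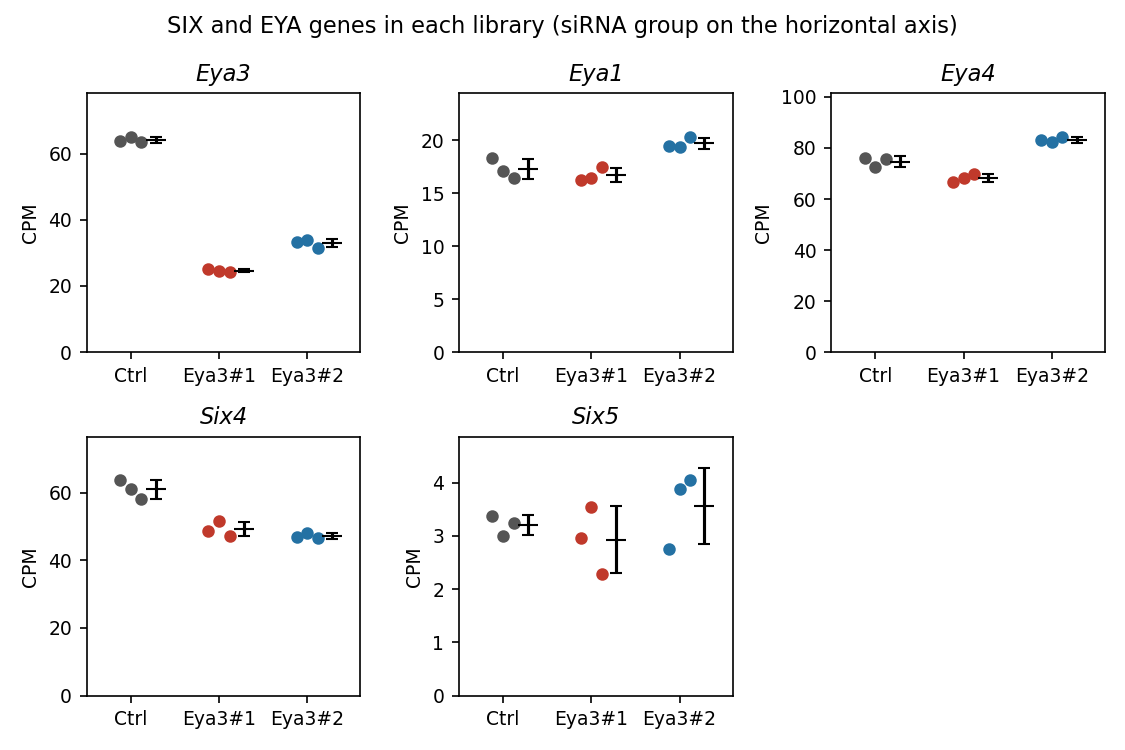
CPM (vertical axis, from 0) of 5 genes of the SIX-EYA-DACH list in each library, grouped by siRNA, with the group mean and SD (n = 3) beside the points. Eya3 averaged 64.2 CPM in si-Ctrl, 24.6 with si-Eya3#1 and 32.9 with si-Eya3#2.

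The genes that moved with both siRNAs address the response that the 2 siRNAs have in common. Both were compared with the same control siRNA, so an effect of that siRNA would also appear in common. Crym (chromosome 7, 120186380 to 120202111), which encodes the thyroid hormone-binding protein mu-crystallin, rose from 2.27 ± 0.201 CPM to 12.8 ± 0.304 and 7.0 ± 0.403, or by 2.48 and 1.62 on the log2 scale (adjusted p = 8.34e-11 and 2.5e-08). Mybpc1 (chromosome 10, 88518279 to 88605152), the slow-type myosin-binding protein C, rose by 2.13 and 1.37 (adjusted p = 5.13e-09 and 1.85e-06). Usp13, a deubiquitinase, rose by 1.17 and 1.00, and Tppp3, a tubulin-binding protein, by 1.10 and 1.31. Fras1, a basement membrane protein, rose by 1.04 and 0.83. The other named genes that rose were Grip2, Fxyd6, Serpinb7, Card10 and Arhgef6, with log2 fold changes of 0.87 to 1.98 with si-Eya3#1 and 0.93 to 1.04 with si-Eya3#2. Igfbp2 (chromosome 1, 72824503 to 72852474), a secreted binder of insulin-like growth factors, fell from 129 ± 7.26 CPM to 51.4 ± 3.28 and 59.9 ± 5.20, or by 1.33 and 1.10 on the log2 scale (adjusted p = 4.24e-10 and 3.82e-09). Ntn5, a netrin family member, fell by 1.67 and 1.46, Dmp1, a mineralised-matrix protein, by 1.67 and 1.27, and the fibrillar collagen Col5a3 by 1.12 and 1.05. Enpp1, which makes pyrophosphate, fell by 1.12 and 0.95. Parm1, Serpinb9g, Spon2 and Fgf5 also fell, with log2 fold changes of -1.51 to -0.94 with si-Eya3#1 and -1.42 to -0.99 with si-Eya3#2. With Eya3 itself these were 10 genes on each side, chosen among those with every knockdown library on the same side of the 3 control libraries.

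In number, 1845 of 14405 tested genes changed in the same direction with both siRNAs, 833 up and 1012 down, and 133 changed in opposite directions (edgeR). Independent lists of these sizes would share 498 in the same direction. In 20 simulated data sets with no effect, which used the same 3 controls for both comparisons, the shared count averaged 0.15 and was at most 1. With no effect of either siRNA few calls can arise. This count therefore does not show what 2 unrelated responses of the real size would share. The same-direction genes made up 62.3% of the calls for si-Eya3#2. Only 71 of them had an absolute log2 fold change of at least 1 with both. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.601 and Spearman rho = 0.539. The simulated r was 0.51 from the shared controls alone, and the covariance was 0.0827 against a simulated 0.0188. The controls are the same 3 libraries in both comparisons and were not split.

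**Figure D2:**
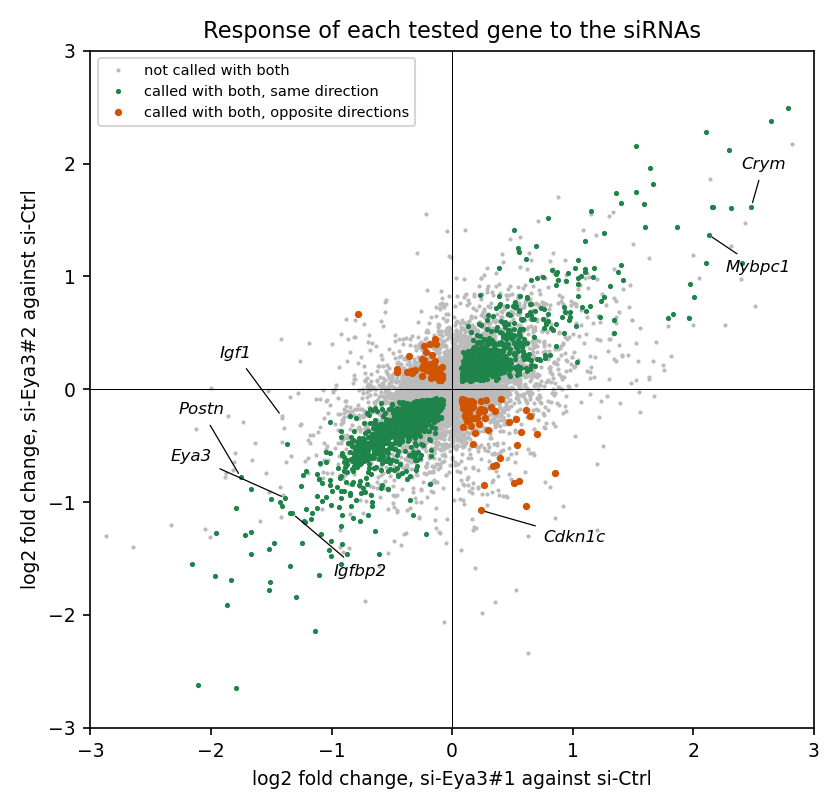
Log2 fold change against si-Ctrl with si-Eya3#1 (horizontal) and with si-Eya3#2 (vertical) for each tested gene; 18 genes lie outside the axes, which end at 3. Colours mark the 1845 genes called in the same direction with both and the 133 called in opposite directions.

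Proliferation genes were the group that fell most with both siRNAs. Of 30 measured cell cycle genes, 28 fell with si-Eya3#1 and 25 with si-Eya3#2 (28 and 27 adjusted over the list alone), with medians of -0.63 and -0.52. The proliferation marker Mki67 fell by 0.87 and 0.66, the topoisomerase Top2a by 0.81 and 0.58, and the mitotic cyclin Ccnb1 by 0.81 and 0.68. Ccnd1, the G1 cyclin, rose by 0.13 and 0.34 (adjusted p = 0.025 and 3e-05). The list was lower by camera (adjusted p = 9.31e-20 and 3.22e-17), but not with an estimated correlation (adjusted p = 0.155 and 0.243). Of 22 DNA damage response genes, 9 fell and 0 rose with si-Eya3#1, and 6 fell and 1 rose with si-Eya3#2 (7 and 1 adjusted over the list alone). The falling members included Brca1, Chek1 and Fancd2, which act in replication-coupled repair. Camera did not call this list for si-Eya3#1 (adjusted p = 0.051), although 7 of 20 alternative fits did, and called it for si-Eya3#2 (adjusted p = 0.0353, and adjusted p = 0.263 with an estimated correlation). That call ended without si-Ctrl replicate 1, si-Eya3#2 replicate 2 or si-Eya3#2 replicate 3, and with the transcript length offset.

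Markers of undifferentiated myoblasts and reserve cells were also lower. Of 14 measured, 12 fell and 1 rose with si-Eya3#1, and 9 fell and 2 rose with si-Eya3#2 (9 and 3 adjusted over the list alone), with medians of -0.47 and -0.20. Pax7, the satellite cell transcription factor, fell by 0.58 and 0.18, and Id3, an inhibitor of myogenic bHLH factors, by 1.37 and 0.49. Sdc4, a surface proteoglycan of satellite cells, rose by 0.16 and 0.30. Camera gave adjusted p = 3.35e-09 and 0.000297. With an estimated correlation the call held for si-Eya3#1 (adjusted p = 0.0494) and was lost for si-Eya3#2 (adjusted p = 0.243). Of 15 Notch pathway genes, 9 fell with si-Eya3#1 and 6 with si-Eya3#2, and 0 rose (9 fell, and 7 fell and 2 rose, adjusted over the list alone). The Notch effectors Heyl and Hey1 fell by 0.75 and 0.57 with si-Eya3#1 and by 0.92 and 0.59 with si-Eya3#2. The receptor Notch3 fell by 0.67 and 0.51, and the ligand Jag1 by 0.69 with both. Camera gave adjusted p = 3.83e-08 and 5.85e-06, and with an estimated correlation adjusted p = 0.0494 and 0.113. Heyl and Hey1 are in both lists. With Eya3 left out of the SIX-EYA-DACH list, the estimated-correlation calls of both lists with si-Eya3#1 ended at adjusted p = 0.0668, because the adjustment runs over all lists.

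Of 13 myogenic transcription factors, 2 rose and 3 fell with si-Eya3#1, and 2 rose and 4 fell with si-Eya3#2 (3 and 5 adjusted over the list alone). The regulators Myod1 and Myog fell by 0.25 and 0.29 with si-Eya3#1 and by 0.19 and 0.27 with si-Eya3#2. Mef2c, a MADS-box factor of late differentiation, rose by 0.83 with si-Eya3#1 and was at 0.14 with si-Eya3#2 (adjusted p = 0.17). The list was not called (camera adjusted p = 0.834 and 0.532). Of 16 myoblast fusion genes, 7 rose and 4 fell with si-Eya3#1 (7 and 5 adjusted over the list alone), and 6 rose and 3 fell with si-Eya3#2 (7 and 3 adjusted over the list alone). Itga3, an integrin subunit, rose by 0.62 and 0.81, while Mymx, the fusion micropeptide, was at -0.09 with si-Eya3#1 (adjusted p = 0.18) and fell by 0.39 with si-Eya3#2. Camera gave adjusted p = 0.0806 and 0.0134, and with an estimated correlation adjusted p = 0.218 and 0.231.

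With si-Eya3#1, most fast and slow fibre genes rose and most matrix genes fell. Of 15 fast fibre contractile genes, 11 rose and 0 fell (11 and 1 adjusted over the list alone), with a median of 0.28. The fast myosin heavy chain Myh4 rose by 0.64 and the fast light chain Myl1 by 0.53. Camera called the list higher (adjusted p = 2.22e-11, and adjusted p = 0.115 with an estimated correlation). Of 12 slow fibre genes 8 rose and 1 fell (median 0.22, camera adjusted p = 5.47e-06, and adjusted p = 0.101 with an estimated correlation). The gene that fell was Myh7, the slow and cardiac beta myosin heavy chain, at -0.69. Of 7 embryonic and neonatal contractile genes 5 rose and 1 fell (adjusted p = 3.09e-05, and adjusted p = 0.155 with an estimated correlation). Of 32 sarcomere genes 17 rose and 4 fell (18 and 4 adjusted over the list alone; camera adjusted p = 0.000134, and adjusted p = 0.338 with an estimated correlation). Of 31 extracellular matrix genes 23 fell and 3 rose (24 and 3 adjusted over the list alone), with a median of -0.40. Postn, a matricellular protein, fell by 1.75, Col1a1 by 0.79 and Fn1 by 0.43, while the proteoglycan Dcn rose by 0.65. Camera gave adjusted p = 3.04e-27, and with an estimated correlation adjusted p = 0.0501. In total 4848 genes changed, 2390 up and 2458 down, of which 248 had an absolute log2 fold change of at least 1 (edgeR).

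Smaller shifts with si-Eya3#1 ran through metabolic and ribosomal genes. Of 40 cytosolic ribosomal protein genes 30 rose and 0 fell (31 and 0 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 2.22e-06, and adjusted p = 0.38 with an estimated correlation). Without 1 library 19 to 31 rose, and 13 over all alternatives at the lowest. Of 45 oxidative phosphorylation genes 25 rose and 2 fell (30 and 2 adjusted over the list alone; camera adjusted p = 3.09e-05, and adjusted p = 0.354 with an estimated correlation). Over all alternatives 14 to 28 of these rose. Correcting for transcript length and GC content, an alternative chosen after seeing the data, ended the camera calls of both lists. Of 21 glycolysis genes 12 rose and 3 fell (13 and 4 adjusted over the list alone; adjusted p = 0.00649, and adjusted p = 0.354 with an estimated correlation). Of 20 tricarboxylic acid cycle genes 8 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.0367, and adjusted p = 0.431 with an estimated correlation). That last call ended under 6 alternatives, including the fits without si-Ctrl replicate 1 and without si-Eya3#1 replicate 2. Of 17 TGF-beta and YAP targets 11 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 0.000143, and adjusted p = 0.273 with an estimated correlation). Of 20 unfolded protein and integrated stress response genes 8 fell and 0 rose (9 and 0 adjusted over the list alone; adjusted p = 0.00709, and adjusted p = 0.354 with an estimated correlation).

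Some named genes changed with si-Eya3#1, were not called in the same direction with si-Eya3#2, and differed between the siRNAs. Their estimates with si-Eya3#2 can still have the same sign. Igf1, a muscle growth factor, fell by 1.41 with si-Eya3#1 (adjusted p = 2.57e-07). With si-Eya3#2 Igf1 was at -0.24 (adjusted p = 0.128), and a per-gene transcript length offset, chosen after seeing the data, gave -0.57 there (adjusted p = 0.0333). Cmya5, the sarcomere-associated myospryn, rose by 1.55 and was at -0.02 with si-Eya3#2. Cyp26b1, which degrades retinoic acid, rose by 0.98, and Clic3, Rundc3a and Adam8 rose by 1.14, 1.07 and 0.94. Slc8a1, a sodium-calcium exchanger, fell by 0.79, and Unc5c, Mcc and Pgf fell by 0.95, 0.90 and 0.86. Of 16 IGF and insulin signalling genes 4 rose and 7 fell with si-Eya3#1 (camera adjusted p = 0.023, and adjusted p = 0.354 with an estimated correlation). The list was not called with si-Eya3#2, where 5 rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.175). The si-Eya3#1 call ended without si-Eya3#1 replicate 2 and with the length and GC correction.

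With si-Eya3#2 fewer genes changed, 2960, with 1440 up and 1520 down and 143 at an absolute log2 fold change of at least 1 (edgeR). Matrix genes fell less evenly. Of 31, 14 fell and 5 rose (16 and 6 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 5.85e-06, and adjusted p = 0.334 with an estimated correlation). Col6a3 fell by 0.91 and Postn by 0.78, while Thbs1, a matricellular glycoprotein, rose by 0.83. Of 15 fast fibre genes 2 rose and 5 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.0353, and adjusted p = 0.641 with an estimated correlation). That call ended without si-Ctrl replicate 2 or si-Eya3#2 replicate 2. Of 32 sarcomere genes 8 rose and 15 fell (camera adjusted p = 0.000573, and adjusted p = 0.462 with an estimated correlation). Without 1 library 2 to 8 rose and 15 fell. Mypn and Tcap, which sit at the Z-disc, fell by 0.58 and 0.36. Of 12 slow fibre genes 5 rose and 2 fell (adjusted p = 0.0706), again with Myh7 lower, at -0.73, and Myl2 higher, at 0.65. Of 17 TGF-beta and YAP targets 9 rose and 2 fell (10 and 3 adjusted over the list alone), among them Tagln at 0.53. The list was called higher (adjusted p = 0.0139, and adjusted p = 0.542 with an estimated correlation), and the call ended without si-Ctrl replicate 2 or si-Eya3#2 replicate 1. Of 40 ribosomal protein genes 7 fell and 0 rose (adjusted p = 0.000573, and adjusted p = 0.734 with an estimated correlation). Without 1 library 4 to 11 fell, and up to 16 over all alternatives.

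Other named genes changed with si-Eya3#2, were not called in the same direction with si-Eya3#1, and differed between the siRNAs. Cdkn1c, the cyclin-dependent kinase inhibitor p57, fell by 1.07 with si-Eya3#2 (adjusted p = 7.12e-09). Cdkn1c rose by 0.24 with si-Eya3#1 (adjusted p = 0.00202), a call that ended with the per-gene transcript length offset at 0.18 (adjusted p = 0.101). Chrdl1, a bone morphogenetic protein antagonist, rose by 1.41, and Dhrs3, which reduces retinal, by 1.40. Crim1, C1ra and Lgr6 rose by 0.99, 0.86 and 0.84. Scara5, a ferritin receptor, fell by 1.42, Fez1 by 1.36, Tmprss11b by 1.27 and the Z-disc protein Myot by 0.89.

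For the next lists, counts are given with si-Eya3#1 and then si-Eya3#2. They were 8 rising and 3 falling, and 9 rising and 2 falling, of 20 p53 targets (9 and 4, and 9 and 3, adjusted over the list alone). Mdm2, the p53 ubiquitin ligase, rose by 0.28 and 0.13. Camera gave adjusted p = 0.0289 and 0.0353, and with an estimated correlation adjusted p = 0.168 and 0.262. The si-Eya3#2 call ended without si-Ctrl replicate 2 or si-Eya3#2 replicate 2, with the transcript length offset, and without si-Ctrl replicate 3 and si-Eya3#1 replicate 3 together. Of 18 immediate early genes 1 rose and 7 fell, and 0 rose and 7 fell (1 and 7 adjusted over the list alone for si-Eya3#2). Egr1 fell by 0.52 and 0.18. Camera gave adjusted p = 0.00032 and 0.0139, and with an estimated correlation adjusted p = 0.155 and 0.334, and the second call ended without si-Ctrl replicate 3. Of 20 calcium handling genes 11 rose and 2 fell, and 4 rose and 5 fell (11 and 3 adjusted over the list alone for si-Eya3#1; camera adjusted p = 0.0105 and 0.822, and adjusted p = 0.155 with an estimated correlation for the first). Of 17 dystrophin glycoprotein complex genes 7 rose and 4 fell, and 8 rose and 2 fell (7 and 5, and 9 and 3, adjusted over the list alone; adjusted p = 0.00704 and 0.0912, and adjusted p = 0.155 with an estimated correlation for the first). Dmd, the dystrophin gene, rose by 0.61 and 0.28. Of 15 neuromuscular junction genes 5 rose and 5 fell, and 3 rose and 4 fell (7 and 5, and 5 and 6, adjusted over the list alone; adjusted p = 0.169 and 0.701). Colq, the collagen tail of acetylcholinesterase, rose by 1.26 and 0.82. Of 18 circadian clock genes 2 rose and 5 fell, and 1 rose and 6 fell (adjusted p = 0.0964 and 0.0139, and adjusted p = 0.243 with an estimated correlation for the second, which ended with the transcript length offset).

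The lists and comparisons that follow in this paragraph had camera adjusted p values of at least 0.0636. With si-Eya3#2, 3 rose and 2 fell of 45 oxidative phosphorylation genes (1 and 2 adjusted over the list alone; camera adjusted p = 0.699). Likewise 5 rose and 1 fell of 21 glycolysis genes (adjusted p = 0.307), 0 rose and 1 fell of 20 tricarboxylic acid cycle genes (0 and 0 adjusted over the list alone; adjusted p = 0.532), and 3 rose and 3 fell of 20 stress response genes (adjusted p = 0.967). Of 7 embryonic and neonatal contractile genes 2 rose and 2 fell (3 and 3 adjusted over the list alone; adjusted p = 0.701). With si-Eya3#1 and si-Eya3#2, fatty acid oxidation had 8 rising and 3 falling, and 4 rising and 2 falling, of 21 genes (adjusted p = 0.0636 and 0.532). Cholesterol synthesis had 2 and 6, and 2 and 4, of 20 (4 and 6 adjusted over the list alone for si-Eya3#1; adjusted p = 0.347 and 0.282). Mitochondrial biogenesis regulators had 4 and 1, and 1 and 0, of 18 (adjusted p = 0.585 and 0.814). Heat shock genes had 7 and 2, and 3 and 1, of 15 (8 and 3, and 3 and 2, adjusted over the list alone; adjusted p = 0.122 and 0.619). Interferon response genes had 4 and 3, and 2 and 1, of 16 (2 and 2 adjusted over the list alone for si-Eya3#2; adjusted p = 0.809 and 0.753). Inflammatory targets had 1 and 4, and 3 and 2, of 13 (adjusted p = 0.237 and 0.961), and the cytokine Il6 fell by 1.5 and 0.98. Atrophy and autophagy genes had 4 and 1, and 3 and 1, of 17 (4 and 2 with each, adjusted over the list alone; adjusted p = 0.175 and 0.701). Wnt targets had 5 and 6, and 5 and 3, of 15 (5 and 7, and 6 and 3, adjusted over the list alone; adjusted p = 0.489 and 0.0675). Lef1, a Wnt effector, fell by 0.92 and 0.37.

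Markers of other cell types that mesenchymal cells can become had no direction in common across the lists. Adipocyte markers had 0 rising and 2 falling, and 2 rising and 1 falling, of 5 measured (camera adjusted p = 0.268 and 0.822). Osteoblast and chondrocyte markers had 0 and 4, and 1 and 2, of 6 (adjusted p = 0.0353 and 0.175, and adjusted p = 0.164 with an estimated correlation for the first). The si-Eya3#1 call ended without si-Eya3#1 replicate 2 and without a filter on low counts. The medians of this list were -0.156 and -0.138. Camera called it for the mean of both, with 0 rising, 3 falling and a median of -0.147. That call held in 8 of 19 alternative fits and was lost with an estimated correlation. Spp1, osteopontin, fell by 0.61 and 0.40. Smooth muscle markers had 2 and 0, and 3 and 1, of 6 (5 and 1 adjusted over the list alone for si-Eya3#2; adjusted p = 0.237 and 0.0708). Of 3 nuclear retained RNAs 1 rose with si-Eya3#1 and 0 changed with si-Eya3#2 (adjusted p = 0.922 and 0.606). Of the immune cell markers only Cd68 and Itgam were measured, at 0.608 and 0.833 CPM, and 0 changed. The mitochondrially encoded list had 0 measured members. Lists without a call that 4 or 5 of 20 alternative fits called were fatty acid oxidation with si-Eya3#1, and slow fibre genes, smooth muscle markers and Wnt targets with si-Eya3#2. List median, mean and camera direction differed in sign for the circadian clock with si-Eya3#1, with a median of -0.058, a mean of 0.043 and a downward test. They differed for fatty acid oxidation with si-Eya3#2, with a median of -0.005 and an upward test. Disagreements of this kind also occurred for myogenic factors, smooth muscle markers and nuclear RNAs with si-Eya3#1. Others were atrophy, adipocyte and IGF genes with si-Eya3#2, inflammatory, TGF-beta and mitochondrial regulator genes for the mean, and p53, fusion and cholesterol genes between the siRNAs.

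**Figure D3:**
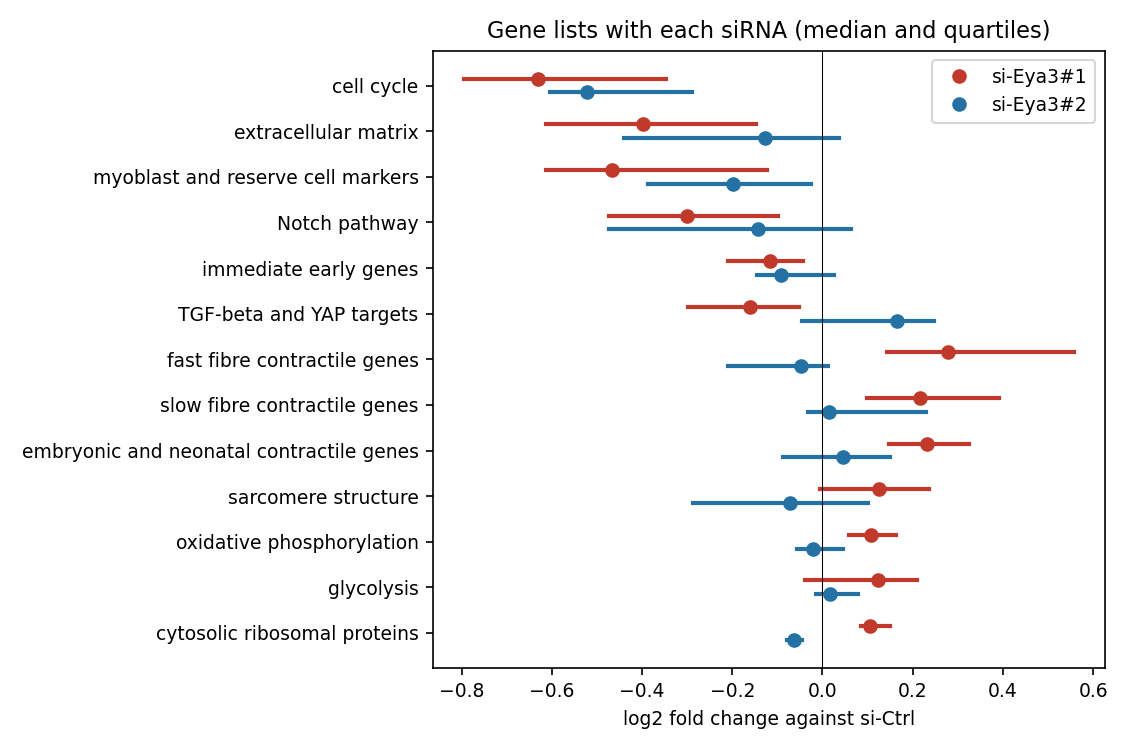
Median log2 fold change against si-Ctrl (points, horizontal axis) and quartiles (bars) of 13 gene lists with each siRNA. Cell cycle medians were -0.63 and -0.52, while fast fibre medians were 0.28 with si-Eya3#1 and -0.047 with si-Eya3#2.

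The mean of both siRNAs against si-Ctrl gives the average difference of the 2 siRNA treatments from the control siRNA. It can include effects of the control siRNA. It can also include effects of 1 Eya3 siRNA alone, since 3511 genes differed between the siRNAs. Igfbp2 fell by 1.21 (standard error 0.0478) and Crym rose by 2.05 (0.0878). In total 4043 genes changed, 1948 up and 2095 down (edgeR). Camera called 18 of the 37 tested lists. With an estimated correlation, the calls that held were the SIX-EYA-DACH network and the Notch pathway, each at adjusted p = 0.0466. With Eya3 left out of its list neither held (adjusted p = 0.332 and 0.0931). Cell cycle genes had a median of -0.58, with 28 falling and 1 rising of 30 (camera adjusted p = 3.44e-23, and adjusted p = 0.157 with an estimated correlation). For this mean 10 rose and 10 fell of the 32 sarcomere genes (13 and 12 adjusted over the list alone; adjusted p = 0.632), with a median of 0.001, a mean of -0.002 and an upward test. The circadian clock list was called lower (adjusted p = 0.028, and adjusted p = 0.181 with an estimated correlation) although its mean was 0.019, a call that ended under 3 of the alternatives chosen after seeing the data.

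The direct comparison of si-Eya3#2 with si-Eya3#1 tests where the siRNAs differed. Fast fibre genes were lower with si-Eya3#2 in 14 of 15 cases and higher in 0, with a median difference of -0.40 (camera adjusted p = 5.61e-28, and adjusted p = 0.0924 with an estimated correlation). Myl1 differed by -0.79 and Myh4 by -0.69. Of 32 sarcomere genes 24 were lower and 1 higher (median -0.25, adjusted p = 1.63e-18, and adjusted p = 0.0953 with an estimated correlation). All 40 ribosomal protein genes were lower (median -0.175, adjusted p = 4.13e-23, and adjusted p = 0.171 with an estimated correlation). Matrix genes were higher with si-Eya3#2 in 24 of 31 cases and lower in 1 (24 and 2 adjusted over the list alone; median 0.23, adjusted p = 1.63e-18, and adjusted p = 0.0953 with an estimated correlation), led by Postn at 0.98. Of 17 TGF-beta and YAP targets 15 were higher and 0 lower (16 and 0 adjusted over the list alone; median 0.37, adjusted p = 1.09e-14, and adjusted p = 0.0953 with an estimated correlation). Of 30 cell cycle genes 4 were higher and 0 lower (3 and 0 adjusted over the list alone), with all 30 estimates above 0 (median 0.135, adjusted p = 0.0058, and adjusted p = 0.546 with an estimated correlation), a call that ended without si-Eya3#2 replicate 1, and 2 to 6 were higher without 1 library. In total 3511 genes differed, 1772 higher and 1739 lower, 148 of them by an absolute log2 fold change of at least 1 (edgeR). Reads on the 5 mitochondrial-like pseudogenes made up 2.80% to 2.86% of the gene totals in si-Ctrl, 2.99% to 3.16% with si-Eya3#1 and 2.61% to 2.70% with si-Eya3#2. H19, an imprinted noncoding RNA of muscle, took 1.44% to 1.53%, 2.15% to 2.17% and 1.53% to 1.69%.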

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

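The tests of knockdown depth as the cause of the difference between the siRNAs were chosen only after the result was seen. So were the counts over other splits for each siRNA against si-Ctrl, for the genes shared by both, for the mean of both and for the lists called between the siRNAs. In 4 lists fixed before the data were examined, the camera calls with the siRNAs had opposite directions and the direct comparison was called. With si-Eya3#2 many members had no call, such as 33 of 40 ribosomal protein genes and 8 of 15 fast fibre genes, and its fast fibre and TGF-beta calls each ended when either of 2 libraries was left out. The median differences of si-Eya3#2 minus si-Eya3#1 were -0.397 for fast fibre genes, -0.252 for sarcomere genes, 0.372 for TGF-beta and YAP targets and -0.175 for cytosolic ribosomal proteins. None of the 4 was called with an estimated correlation (adjusted p = 0.0924, 0.0953, 0.0953 and 0.171). With the preset correlation the direct comparison stayed called for each of the 4 in the fits without 1 library.

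The lower cell cycle genes with both siRNAs had a median of -0.58 for the mean of both. Scaling choices left it at -0.585 or lower, the length and GC correction at -0.604, and the fits without 1 control library at -0.513 or lower, which argues against each as the whole cause. Another explanation is a lower number of undifferentiated, still dividing myoblasts in the knockdown wells. Of the 4 markers named for it, Pax7 and Cd34 fell, at -0.38 and -0.23. The other 2 did not fall, Myf5 at 0.17 (edgeR adjusted p = 0.0501) and Sdc4 at 0.23 (edgeR adjusted p = 3.77e-05). The bound set in advance took such a result as evidence against. It was judged too lenient only after the result was seen, because 10 of the 14 listed markers fell and Sdc4 is also expressed by other cells. That list was not called for the mean with an estimated correlation. A change in cell composition and a change within cells therefore cannot be told apart here.

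The ribosomal protein genes were lower with si-Eya3#2 than with si-Eya3#1. The length and GC correction brought their median from -0.175 to -0.11 and the number called from 40 to 31 of 40, so such a bias may make up part of the difference but not all of it, with a thin margin to the bound of -0.10 set in advance. After it the medians were 0.046 with si-Eya3#1 and -0.066 with si-Eya3#2 against si-Ctrl. Scaling choices left the difference at -0.174 or lower, and leaving out ribosomal RNA-like reads with library totals left it at -0.156 with 36 called. The part that stays open includes off-target effects of either siRNA, which were not tested.

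Muscle and matrix genes responded differently to the siRNAs, of which si-Eya3#1 lowered Eya3 RNA at 96 h more. Eya3 protein and the time course of the knockdown are not part of these data. If the response of each gene grew with knockdown depth alone, si-Eya3#2 would move no gene further than si-Eya3#1 or the other way. Of 65 contractile and sarcomere genes, 44 were called between the siRNAs at an adjusted p under 0.01, and 20 of these also with si-Eya3#2. Of these 20, 15 moved further or the other way with si-Eya3#2, where false calls allowed 0.31 on average. The genes called between the siRNAs and not with si-Eya3#2 are left out of the 20, and depth alone could give them. Genes that move together can give more false calls at once. For these 15 genes, the values argue against a response that grows with the depth of Eya3 RNA at 96 h alone. Of 31 matrix genes, 20 were called between the siRNAs and 12 of these also with si-Eya3#2. Of these 12, 4 moved further or the other way with si-Eya3#2, where false calls allowed 0.18, and these 4 go against depth alone. For a verdict on a whole set, most of the genes called in both comparisons had to do so. That bound was chosen after the counts were seen. Set against all genes called between the siRNAs, neither 15 of 44 nor 4 of 20 would be most. The matrix medians of -0.40 with si-Eya3#1 and -0.13 with si-Eya3#2 are also what a shallower knockdown would give. For the matrix genes as a set, depth and other causes therefore cannot be told apart. Length and GC bias is argued against by the fast fibre median of -0.401 and the matrix median of 0.165 after the correction. Sequence-specific effects of either siRNA could underlie the muscle gene differences, and stay open because no rescue or further siRNA was analysed here.

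For the genes changed with each siRNA, the 10 splits of 6 libraries are too few for a share under 0.05. With si-Eya3#1, 1 split, the real one, reached the real value of 4772 in a fit of these groups only, and the highest other gave 1. With si-Eya3#2, 1 split reached 2936 and the highest other gave 1, and between the siRNAs 1 split reached 3262 and the highest other gave 0. The same holds for the lists called, with 21 against 16 for si-Eya3#1, 15 against 8 for si-Eya3#2 and 17 against 14 between the siRNAs. The split that called 14 lists called 0 genes (edgeR). For the genes shared by both, 1 of 100 splits, the real one, reached 1845. The highest other gave 1159, with the si-Eya3#1 libraries taken as the control group. This argues against a chance assignment of libraries to groups. Splits that mix the groups have more spread, so the test cannot decide whether the siRNAs share a response. For the mean of both, 2 of 84 splits reached the real 2149 in a fit of 2 groups, which argues against a chance assignment. The other, which set the si-Eya3#1 libraries against the rest, gave 2649, and points to the si-Eya3#1 group as the most distinct. Splits that mix the groups have more spread here too, so this count does not show what the siRNAs share. For the lists called for the mean, the fit of 2 groups, which counts the difference between the siRNAs as spread, called 8 where the fit of 3 groups called 18. Of 84 splits, 40 reached the real 8 and the highest other gave 19, so chance cannot be excluded. For the correlation across genes, 19 of 100 splits reached 0.6007 and the highest other gave 0.7536. That split kept the 3 si-Ctrl libraries as the control group and mixed only the siRNA libraries. It therefore holds the real difference from si-Ctrl, and the test cannot decide whether the correlation arose by chance.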

How the results depend on the processing

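The transcript length offset, the length and GC correction, the 2 exclusions of ribosomal RNA-like genes, the SIX-EYA-DACH list without Eya3 and the joint exclusion of si-Ctrl replicate 3 and si-Eya3#1 replicate 3 were chosen only after the results were seen. Eya3 stayed lower in every fit, at -1.48 to -1.35 with si-Eya3#1 and -1.13 to -0.93 with si-Eya3#2, and the cause of this spread was not tested. The counts of changed genes stayed within 1.5 times the reported ones in all fits except those that also required an absolute log2 fold change of at least 1. That gave 248 for si-Eya3#1, 143 for si-Eya3#2, 71 for both in the same direction, 146 for the mean and 148 between the siRNAs, by its construction. An estimated correlation left 3 lists called for si-Eya3#1, 0 for si-Eya3#2 and 2 for the mean, since it allows for genes of a list moving together. With Eya3 left out of its list the numbers called were 21, 13 and 18, and 0 for each with an estimated correlation. The length and GC correction left 11 lists called for the mean; the cause was not tested. The correlation across genes was 0.5215 without a filter and 0.482 with DESeq2, and 0.4972 to 0.6651 without 1 library; the cause was not tested. Same-numbered replicates of different groups were no more alike than others (r of -0.088 to 0.03 against -0.084 to 0.088), and the file of si-Eya3#2 replicate 1 carries the number 4 where its label, followed here, says 1. The replicate block gave 4779, 2958, 1844, 4043 and 3480 genes.

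Of 7866 alternative values for 358 values of named genes, 7557 kept direction and side of the threshold, 202 lost and 57 gained the call, and 50 changed sign. Of these 50, 49 had an adjusted p of at least 0.05 in both fits. The exception was Rplp1 with si-Eya3#1 under the length and GC correction, at -0.06603 (adjusted p = 0.0348, and 0.0348 to 0.977 over its alternatives). The values that changed sign ran from -0.1673 to 0.2341, and the cause was not tested. With the transcript length offset Cd68 was at 0.06326 and Neat1 at -0.007328 with si-Eya3#2, and Smtn at 0.036 with si-Eya3#1. With the joint exclusion of 2 libraries Kcnq1ot1 was at -0.1301, Neat1 at -0.02187 and Sucla2 at -0.0005199 with si-Eya3#2. The same exclusion gave Six5 at 0.02831, Scara5 at -0.005546, Chrdl1 at -0.06334 and Rplp1 at -0.01082 with si-Eya3#1. The length and GC correction gave Smtn 0.006141 with si-Eya3#1 and Kcnq1ot1 -0.01517 with si-Eya3#2. Library totals gave Sucla2 -0.006525 with si-Eya3#2 and Rplp1 -0.001654 with si-Eya3#1, and without ribosomal RNA-like genes -3.437e-05 and -0.01695. The replicate block gave Cmya5 0.006785 with si-Eya3#2.

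Without 1 library, ranges with si-Eya3#1 were -0.282 to 0.02717 for Six5, -0.1166 to 0.3223 for Chrdl1, -0.1528 to 0.1043 for Dhrs3 and -0.004029 to 0.3093 for Lgr6. They were -0.007582 to 0.2287 for Scara5, -0.112 to 0.02597 for Fez1, -0.09837 to 0.2421 for Myot and -0.09163 to 0.07611 for Tagln. They were -0.03707 to 3.77e-05 for Smtn, -0.1673 to 0.3658 for Itgam, -0.3252 to 0.04116 for Cd68 and -0.002096 to 0.02324 for Rplp1. With si-Eya3#2 they were -0.2977 to 0.2341 for Cmya5, -0.01247 to 0.02212 for Sucla2, -0.01114 to 0.007061 for Suclg1 and -0.395 to 0.0808 for Cd68. They were -0.01738 to 0.1426 for Neat1, -0.1256 to 0.3427 for Kcnq1ot1, -0.01646 to 0.0183 for Rpl5 and -0.04925 to 0.004949 for Rpl14. Of 152 counts of rising or falling list members with each siRNA, 66 left 1.5 times the reported count in a fit without 1 library, 56 of them counts under 5. With si-Eya3#1, 3 to 8 heat shock (7 reported), 5 to 8 fatty acid (8), 3 to 5 Wnt (5) and 0 to 3 interferon genes (4) rose. With si-Eya3#2, 1 to 5 IGF (5), 3 to 5 glycolysis (5), 3 to 6 Wnt (5), 0 to 3 inflammatory (3) and 0 to 2 interferon genes (2) rose, and 3 to 5 calcium handling (5) and 1 to 6 cholesterol genes (4) fell. Depth limits genes of low level, such as Cd68 and Itgam at 0.608 and 0.833 CPM.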

Other observations

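The tests on imprinted genes and on myosin heavy chains were chosen only after results for H19, Cdkn1c and Myh7 were seen. Several imprinted genes, which are expressed from 1 parental copy, were among the genes called. H19 rose by 0.55 with si-Eya3#1 and 0.14 with si-Eya3#2, while its neighbour Igf2, a fetal growth factor, fell by 0.24 and 0.49. Mest fell by 0.36 and 0.25, Copg2 by 0.25 with both, and Peg3 rose by 0.21 and 0.19. With si-Eya3#2 alone Peg10 rose by 0.72 and Plagl1, a zinc finger factor, fell by 1.02 (adjusted p = 4.21e-07 and 0.00107), against -0.10 and 0.10 with si-Eya3#1 (adjusted p = 0.244 and 0.687).

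A hypothesis that imprinted genes respond as a group was tested on a list of 40, of which 29 were measured. With si-Eya3#1 5 rose and 5 fell, and with si-Eya3#2 4 rose and 5 fell. Of all tested genes 33.7% and 20.5% were called, so with si-Eya3#1 imprinted genes were called about as often as others. The higher share with si-Eya3#2 was not tested. The limma camera test across all 14405 genes gave a value of 0.826 for the unadjusted p of the mean of both, which decides nothing, because members moved in both directions.

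A hypothesis that slow and cardiac type myosin heavy chains fell relative to the others was tested on the share of Myh7 and Myh6 among the reads of 9 heavy chain genes. The share was 8.88%, 8.62% and 8.59% in the si-Ctrl libraries, 5.38%, 4.77% and 5.21% with si-Eya3#1, and 5.76%, 6.03% and 5.66% with si-Eya3#2. The test decides nothing, because the fall of Myh7 that prompted it also lowers this share. Myh6, the other member of the share, fell by 0.76 and 0.82 with si-Eya3#1 and si-Eya3#2 (edgeR adjusted p = 1.84e-09 and 2.4e-09). The neonatal Myh8 rose by 0.59 and 0.34. Of the remaining heavy chain genes none was called in the same direction with both, and the slow Myh7b was at 0.13 and -0.13 without a call. The slow genes Myl2 and Mybpc1 rose, by 0.62 and 2.13 with si-Eya3#1 and by 0.65 and 1.37 with si-Eya3#2. Reads shared between heavy chain paralogues could shift these shares and were not tested.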
